A study of Mus musculus with 9 samples.

How the data were processed

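RNA from sorted bone marrow cells of 10-week-old C57BL/6 mice was measured in 9 libraries, 3 from each of 3 populations, with 10000 sorted cells per replicate per the labels' protocols. The protocols give male mice and the series description mixed sexes, and the Y-linked genes and Xist are given in the report. The replicates are not stated to be from separate animals.

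The authors deposited a table of CPM values per transcript, with Ensembl transcript models and 1 column per library, per the file headers. The labels name STAR, Bowtie2 and build GRCm38, without versions or roles, and the counting program, the denominator and the filter are not given in the sources used here. The table lists 58094 transcripts of 20635 gene symbols and 20679 gene identifiers, and 40 symbols have more than 1 identifier. A transcript without reads is listed at 0.0001, so that this offset was subtracted. The smallest step between values is 0.0485 to 0.0646 CPM, depending on the library. Each listed transcript has at least 10.0 reads summed over the 9 libraries. If the constant is the one CPM implies, 1 CPM equals 15.5 to 20.6 reads, and the listed transcripts hold 51.5 to 54.5% of that total. The design foresaw a count test if the file held counts. Whole reads came back for only 65.1 to 67.2% of low genes (within 0.1 read), at 60.3 to 61.6% of short and 72.6 to 76.1% of long genes with 1 listed transcript, so the values were not taken as counts, no count test was run and the unit is CPM. Depth allows 3 reads at 0.146 to 0.194 CPM, and 12988 to 13612 genes per library reached 1 CPM.

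Values were summed per gene symbol, and genes with at least 1 CPM in at least 3 of 9 libraries were kept (13997). Coordinates come from the file, where the end is the listed stop minus 1. Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with trend, not robust) on log2 of CPM plus 1, with all 9 libraries in 1 fit and a BH-adjusted p under 0.05. Tables and figures used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Sdc2 was also compared with an exact two-sided permutation test. Gene lists were tested with limma camera at the preset correlation of 0.01, with camera at an estimated correlation and with fry, BH-adjusted over the lists of a comparison. Lists with fewer than 5 tested members had no set test. The position of Parent is the slope of Parent minus Syndecan-2- on Syndecan-2+ minus Syndecan-2- over the genes changed between those populations, and 100 draws simulated a Parent unchanged from Syndecan-2-.

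The comparisons, tests, gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. Named genes are Sdc2, the 10 largest rises and 10 largest falls between Syndecan-2+ and Syndecan-2- among genes called with values that do not overlap and with a gene symbol that is not a clone or model name, 5 and 5 for each other comparison, up to 4 members per list with the smallest p (every called member if there are at most 8), and Cdkn1c, Cdkn1a, Procr, Slamf1, Cd48, Flt3, Cd34, Kit, Ly6a and Mki67. Not every gene that the rule names is printed. Other members are named where a count is 5 or fewer or as examples of a list, such as Pf4, Csf1r, Elane, Hoxa9, Tyms, Chaf1b, Tfrc, Sdc3, Sulf2 and Agrn, and these were chosen after their values were seen. Lists of plasma cell, mature B cell and macrophage markers were added after the data were seen. Of 5 macrophage markers tested, 2 rose (Axl and Slc40a1) and 2 fell (Csf1r and Cd68), with a median of 0.00.

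The alternative settings fixed in this way were pseudocounts of 0.1 and 5, no filter and a minimum of 10 CPM, TMM rescaling (trims of 0.3 and 0.05), quantile normalization, eBayes without trend or robust, the 6 libraries compared alone, the replicate number as a block, each library left out in turn, a BH threshold of 0.1, and transcripts in place of genes. Rescaling to the same sum over listed transcripts, TMM rescaling together with the block, quantile normalization for the list tests, the CPM scale for the position of Parent, and leaving out each library for Sdc2 and for the position of Parent were chosen after seeing the data.

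Whether the replicate numbers pair samples was checked from the deviations of each library from its population mean. Same-numbered libraries correlated at 0.117 to 0.259 (9 pairs) and others at -0.206 to 0.00483 (18 pairs), so the numbers pair samples, and the block is reported for lists with a set test and, where it changes the call, for genes named as not called. Replicates were checked to be separate libraries. Their spread was 2.94 to 4.09 times counting noise, and 0 pairs were identical. On simulated data with 200 changed genes the pipeline recovered 46.5% at 1.5-fold, 84.5% at 2-fold and all at 4-fold. Unchanged genes made up 4.12%, 3.43% and 4.31% of calls, and 0 genes were called with no change. Whether these rates hold in the real libraries was not tested.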

Results

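RNA was sequenced from mouse bone marrow cells sorted on the stem cell gate KSL CD34- (positive for c-Kit and Sca-1, negative for lineage markers and for CD34), at 10000 sorted cells per library. The 9 libraries form 3 populations of 3. The Parent population is the whole KSL CD34- gate, the Syndecan-2+ and Syndecan-2- populations are the parts of that gate with and without the surface proteoglycan Syndecan-2. Values are CPM, reads of a transcript scaled to a common total, summed per gene symbol, given as mean ± SD with n = 3 libraries throughout, and positions are those of genome build GRCm38. By the smallest step between values, 1 CPM equals 15.5 to 20.6 reads depending on the library, and the listed transcripts hold 51.5 to 54.5% of the total that CPM implies. A count of 3 reads equals 0.146 to 0.194 CPM, so differences below that level were not detectable at this depth. Such floors cover counting error only. Replicates are not stated to be from separate animals, so p-values measure only the spread between these samples, which may be technical. "Higher" or "lower", "rose" or "fell" mark genes past a BH-adjusted p of 0.05 in limma over all 13997 genes tested, unless only values are given. Bracketed values after a setting or a library left out are log2 fold changes there, unless named or set after a mean.

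The sorted gene was measured first. Sdc2 (ENSMUSG00000022261, chromosome 15, 32920723 to 33034730) encodes the surface proteoglycan used for the sort. It stood at 0.332 ± 0.137 CPM in Syndecan-2- libraries, 1.75 ± 0.290 CPM in Parent libraries and 4.58 ± 0.571 CPM in Syndecan-2+ libraries, and the values of the 3 populations did not overlap. The difference between the sorted populations was 4.25 CPM, with a two-sided exact permutation p of 0.1, the smallest that 3 libraries against 3 can give. The Syndecan-2+ minus Parent difference was 2.84 CPM and the Syndecan-2- minus Parent difference was -1.41 CPM, each with the same exact p of 0.1. In limma over all genes Sdc2 was higher in Syndecan-2+ than in Syndecan-2- libraries by 2.07 on the log2 scale (SE 0.19, adjusted p = 1.80e-07).

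The main comparison, Syndecan-2+ against Syndecan-2-, asks how stem cell gate cells with the proteoglycan differ from those without it. Stem cell genes were higher with Syndecan-2. Vwf (ENSMUSG00000001930, chromosome 6, 125546774 to 125686679), the von Willebrand factor gene of platelet-primed stem cells, rose from 6.28 ± 0.959 to 94.2 ± 11.2 CPM, 15.0-fold (log2 3.71, SE 0.11, adjusted p = 1.56e-13). Progenitor genes were lower. Flt3 (ENSMUSG00000042817, chromosome 5, 147330741 to 147400489), the cytokine receptor of multipotent progenitors, fell from 279 ± 16.3 to 19.9 ± 3.16 CPM (log2 -3.75, SE 0.09, adjusted p = 3.81e-14). Dntt (ENSMUSG00000025014, chromosome 19, 41029275 to 41059523), the terminal transferase of lymphoid priming, fell from 484 ± 29.5 to 37.0 ± 14.7 CPM (log2 -3.76, SE 0.19, adjusted p = 1.79e-10).

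Of the 13997 genes, 4205 (30.0%) changed between the sorted populations, 2874 higher and 1331 lower in Syndecan-2+. At 2-fold or more in CPM plus 1, 764 were higher and 382 lower. With TMM rescaling the split was 1990 higher and 1993 lower, and with quantile normalization 1995 and 1873. With transcripts in place of genes it was 1556 higher and 977 lower, and with a minimum of 10 CPM 1749 higher and 860 lower, with fewer genes tested. TMM moved the median log2 fold change of all genes from 0.10 to -0.01, a shift of -0.11, and small changes have to be read against that shift. The values of both populations did not overlap for 42.5% of tested genes, against 10% by chance for 3 against 3.

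The stem cell list was higher almost throughout. Of 29 long-term HSC genes tested, 28 rose and 1 fell, with the same counts adjusted over the list alone, and the list was called in camera (adjusted p = 2.96e-23, and adjusted p = 0.0418 with an estimated correlation). Mecom, a transcription factor of stem cell maintenance, rose from 13.2 ± 0.733 to 68.3 ± 7.09 CPM. Fgd5, used as a stem cell reporter gene, rose from 3.06 ± 0.422 to 31.2 ± 3.10 CPM. Procr, the protein C receptor used to sort stem cells, rose from 3.03 ± 0.394 to 13.2 ± 0.542 CPM, and Slamf1, which encodes the stem cell marker CD150, rose from 2.54 ± 0.284 to 12.5 ± 2.46 CPM. Hoxa9, a homeobox gene of stem and progenitor growth, was the 1 member that fell, from 45.4 ± 2.29 to 29.7 ± 5.63 CPM. Hoxa9 and other members named because a count is 5 or fewer were chosen after their values were seen. Kit, the stem cell factor receptor of the gate, rose from 164 ± 12.7 to 259 ± 17.0 CPM. Ly6a, which encodes Sca-1, stood at 5.46 ± 1.01 and 7.54 ± 0.916 CPM and was not called (adjusted p = 0.0627, or 0.0337 with the replicate number as a block and 0.0289 without Syndecan-2- library 3).

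The progenitor list was lower almost throughout. Of 20 multipotent and lineage-primed progenitor genes tested, 0 rose, 18 fell and 2 were not called, with the same counts adjusted over the list alone. Camera called the list (adjusted p = 1.41e-26), with an adjusted p = 0.0521 with an estimated correlation. Cd34, the marker selected against in the gate, fell from 203 ± 11.7 to 44.6 ± 6.36 CPM. Satb1, a chromatin organiser of lymphoid priming, fell from 187 ± 9.58 to 24.6 ± 2.14 CPM. Csf1r, the macrophage growth factor receptor, fell from 23.0 ± 2.45 to 1.42 ± 0.723 CPM. Cd48, used to part progenitors from stem cells, fell from 15.8 ± 2.83 to 4.18 ± 0.773 CPM. The members not called were Elane, a granule protease, at 23.5 ± 4.53 and 34.7 ± 18.1 CPM (adjusted p = 0.182), and Ms4a3. With the replicate number as a block Elane was called higher (log2 0.45, adjusted p = 0.00356).

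**Figure D1:**
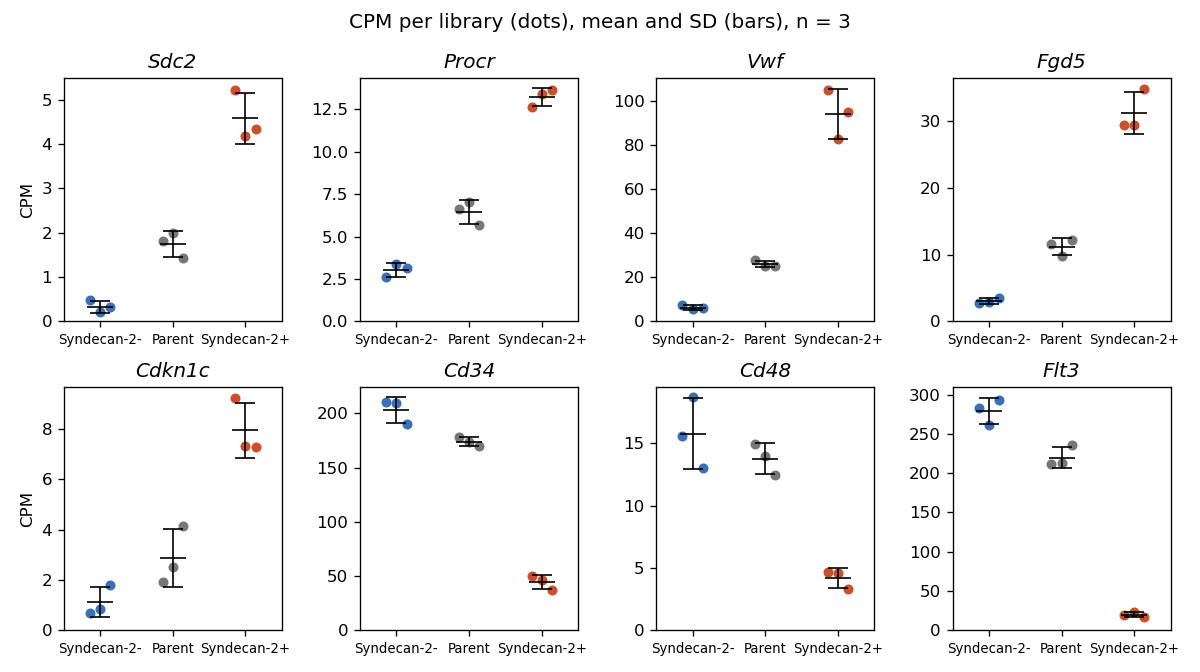
CPM per library for Sdc2, stem cell and progenitor genes in Syndecan-2-, Parent and Syndecan-2+ libraries, with dots for the 3 libraries of each population and bars for mean and SD. Vwf stood at 6.28, 26.0 and 94.2 CPM and Flt3 at 279, 219.9 and 19.9 CPM in these populations.

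The other large falls under the naming rule were in genes of different functions. Kcng1, a potassium channel subunit, fell from 21.8 ± 4.13 to 0.983 ± 0.366 CPM, and Sema3d, a secreted guidance factor, fell from 16.04 ± 2.40 to 0.563 ± 0.397 CPM. Cd33, a sialic acid binding receptor of myeloid cells, fell from 19.1 ± 3.504 to 0.868 ± 0.677 CPM. Tlr7, the endosomal RNA sensor, fell from 17.6 ± 4.42 to 0.741 ± 0.202 CPM. Emp1, a membrane protein gene, fell to 1.46 ± 0.211 CPM, Cnn3, a calponin, to 3.66 ± 1.06 CPM and Card6, a caspase recruitment domain gene, to 1.22 ± 0.588 CPM. The Syndecan-2+ mean was 0.359 CPM without library 2 for Sema3d and 0.544 CPM without library 1 for Cd33.

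Immunoglobulin genes made up 9 of the 10 largest rises under the naming rule, if Jchain, the joining chain of secreted antibodies, is counted with them. Igkc (ENSMUSG00000076609, chromosome 6, 70726435 to 70726966), the kappa constant region, rose from 0.507 ± 0.792 to 428 ± 90.5 CPM (log2 8.25, SE 0.24, adjusted p = 1.56e-13). Igha (ENSMUSG00000095079, chromosome 12, 113254830 to 113260236), the IgA constant region, was listed at 0 in Syndecan-2- libraries and at 145 ± 38.4 CPM in Syndecan-2+ libraries, at least 924-fold higher against a floor of 3 reads per library. Jchain rose from 0.365 ± 0.398 to 116 ± 21.7 CPM. Without Syndecan-2- library 3 the Syndecan-2- mean was 0.0508 CPM for Igkc and 0.152 CPM for Jchain. Iglc1, Iglc3, Igkv1-135, Ighv11-2, Igkv12-89 and Iglv1 rose too, and the V genes are uncertain because paralogs share reads. Of 145 immunoglobulin genes listed, Jchain included, 47 were tested, 40 rose and 3 fell (Ighd, Ighv1-23 and Ighv1-77). Their summed CPM was 134 ± 14.7 in Syndecan-2-, 470.4 ± 23.6 in Parent and 1733 ± 222 in Syndecan-2+ libraries. Tgm2, a transglutaminase and the other gene among the 10, rose from 4.72 ± 0.552 to 77.9 ± 9.64 CPM.

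Megakaryocyte and erythroid genes were higher. Of 17 megakaryocyte and platelet genes tested, 16 rose, 0 fell and 1 (Plek) was not called, with 16 and 0 adjusted over the list alone, and camera called the list (adjusted p = 2.71e-13, and adjusted p = 0.0418 with an estimated correlation). Itga2b, which encodes the platelet integrin CD41, rose from 40.6 ± 2.25 to 153 ± 4.51 CPM. Zfpm1, the GATA cofactor FOG1, rose from 93.1 ± 5.66 to 305 ± 6.22 CPM. Pf4, a platelet chemokine, rose from 4.85 ± 1.07 to 41.1 ± 3.27 CPM. Of 10 erythroid genes tested, 8 rose, 1 fell (Tfrc) and 1 was not called (Tspo2), with 9 and 1 adjusted over the list alone. Camera called this list (adjusted p = 1.72e-05), with an adjusted p = 0.256 with an estimated correlation. Car2, a carbonic anhydrase, rose from 67.3 ± 7.19 to 198 ± 2.01 CPM, Aqp1, a water channel, from 11.7 ± 1.46 to 44.2 ± 4.30 CPM, Car1 from 8.36 ± 1.51 to 33.7 ± 3.69 CPM and Hemgn, a nuclear factor of erythroid growth, from 9.18 ± 0.486 to 21.2 ± 1.55 CPM. Tspo2 was called higher without Syndecan-2- library 1 (0.82).

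DNA replication genes and mitosis genes differed in direction. Of 28 DNA replication genes tested, 2 rose (Tyms and Chaf1b), 7 fell and 19 were not called, with 2 and 7 adjusted over the list alone and with 1 higher and 15 lower under TMM rescaling. Camera called the list lower (adjusted p = 0.000763), with an adjusted p = 0.477 with an estimated correlation. The helicase genes Mcm6 and Mcm7 fell from 235 ± 6.27 to 189 ± 2.55 CPM and from 116 ± 7.16 to 89.7 ± 5.56 CPM, and Uhrf1, which maintains DNA methylation, fell from 89.6 ± 5.20 to 69.8 ± 1.34 CPM. Of 28 mitosis genes tested, 14 rose, 1 fell and 13 were not called, with 17 and 1 adjusted over the list alone and with 7 higher and 1 lower under TMM rescaling. Camera called the list higher (adjusted p = 0.00471), with an adjusted p = 0.608 with an estimated correlation. Hmmr, a spindle protein gene, rose from 19.6 ± 1.46 to 29.6 ± 1.71 CPM and Ccnb1, which encodes cyclin B1, from 10.3 ± 1.01 to 15.8 ± 1.23 CPM. Ube2c, a mitotic ubiquitin enzyme, rose from 10.9 ± 0.894 to 16.3 ± 2.29 CPM, and Kif23, a kinesin of cytokinesis, fell from 44.1 ± 1.35 to 32.8 ± 1.17 CPM. Mki67, the proliferation marker, rose from 414 ± 27.5 to 509 ± 54.6 CPM (log2 0.30), a call lost under TMM rescaling (0.18, adjusted p = 0.102) and without Syndecan-2+ library 1 (0.21, adjusted p = 0.0607). Tyms lost its call under TMM rescaling (0.24), under quantile normalization (0.23) and without Syndecan-2- library 1 or Syndecan-2+ library 3 (0.30).

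Of 24 cell cycle entry genes and CDK inhibitors tested, 6 rose, 7 fell and 11 were not called, with 6 and 8 adjusted over the list alone. The list was not called, and its median of 0.02 and mean of 0.10 were positive where the camera direction was lower, with a median of -0.10 under TMM rescaling. Cdkn1c, the inhibitor p57 of quiescent stem cells, rose from 1.11 ± 0.591 to 7.95 ± 1.10 CPM, and Cdkn2d, the inhibitor p19, rose from 8.68 ± 1.49 to 16.9 ± 2.12 CPM. Mycn, a growth transcription factor, rose from 20.3 ± 0.576 to 62.2 ± 9.54 CPM. Gfi1, a repressor of stem cell cycling, fell from 9.80 ± 0.761 to 4.68 ± 1.54 CPM. Cdkn1a, the inhibitor p21, stood at 16.5 ± 2.62 and 12.8 ± 1.45 CPM (log2 -0.34, adjusted p = 0.0556, not called). It was called lower under TMM rescaling, quantile normalization or the replicate block (adjusted p = 0.0132 to 0.0175). The same held without Parent library 1 or Syndecan-2- library 2 (adjusted p = 0.0499 and 0.0278).

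Other proteoglycan genes changed in both directions where Sdc2 was higher. Of 25 syndecans, glypicans and heparan sulfate enzymes tested, 6 rose, 5 fell and 14 were not called, with 6 and 6 adjusted over the list alone and with 5 higher and 9 lower under TMM rescaling. The list was not called, with a median of 0.13 against a mean of -0.06 and a lower camera direction, and with a median of -0.04 under quantile normalization. Sdc1, a syndecan of epithelial and plasma cells, fell from 17.0 ± 2.29 to 3.91 ± 0.863 CPM and Sdc4, a widely expressed syndecan, from 9.89 ± 1.48 to 3.47 ± 0.405 CPM. Hpse, the heparanase gene, fell from 6.65 ± 0.245 to 0.922 ± 0.440 CPM, and Sdc3 and Sulf2 also fell. Besides Sdc2, Agrn, Ext2, Ndst2, Hs2st1 and Hs3st1 rose, at log2 values of 0.32 to 0.73. Under quantile normalization 4 of the 25 were higher and 8 lower. Hs2st1 lost its call under TMM rescaling (0.20), under quantile normalization (0.18) and without Syndecan-2- library 1 or 2 or Syndecan-2+ library 1 (0.24 to 0.30). Hs3st1 lost its call under quantile normalization (0.55) and without Syndecan-2- library 2 or Syndecan-2+ library 3 (0.58 to 0.59). Sulf2 lost its call with pseudocount 5 (-0.19), without a filter and with the 6 libraries alone (-0.51) and without any 1 Parent library, Syndecan-2- library 1 or 3 or any 1 Syndecan-2+ library (-0.56 to -0.43).

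Marker lists of other cell types gave mixed results. Of 5 neutrophil and monocyte genes tested, 1 rose, 3 fell and 1 (Ly6c2) was not called, with 1 and 3 adjusted over the list alone, and camera called the list lower (adjusted p = 0.00471), with an adjusted p = 0.225 with an estimated correlation. Lyz2, a lysozyme, rose from 23.1 ± 1.32 to 34.5 ± 2.11 CPM. Itgam, an integrin subunit, fell from 16.3 ± 1.95 to 3.15 ± 1.21 CPM, Csf3r, the G-CSF receptor, from 37.2 ± 1.34 to 17.6 ± 2.98 CPM and Ccr2, a chemokine receptor, from 6.81 ± 1.05 to 1.61 ± 0.872 CPM. Of 9 B, T and NK cell genes tested, 0 rose, 5 fell and 4 were not called, with 0 and 5 adjusted over the list alone, and camera called the list (adjusted p = 0.000164, and adjusted p = 0.0418 with an estimated correlation). Ebf1, a B lineage transcription factor, fell from 5.08 ± 0.687 to 0.846 ± 0.536 CPM (0.538 without Syndecan-2+ library 1), Lck, a T cell kinase, from 17.6 ± 4.27 to 8.84 ± 0.682 CPM, Pax5, which commits B cells, from 3.03 ± 1.26 to 0.265 ± 0.184 CPM and Igll1, a surrogate light chain, from 1.70 ± 0.643 to 0.141 ± 0.0383 CPM. The fall of Cd4, a T cell coreceptor, from 1.91 ± 0.237 to 0.901 ± 0.115 CPM (log2 -0.61, adjusted p = 0.0433) was lost without any 1 of the Syndecan-2- or Syndecan-2+ libraries or Parent library 3, at log2 values of -0.68 to -0.56, with pseudocount 5 (adjusted p = 0.0537) and without a filter on low values (adjusted p = 0.0597). Ly6c2 was called lower without Syndecan-2+ library 2 (-0.78).

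Of 7 endothelial genes tested, 3 rose, 2 fell and 2 were not called, with 3 and 2 adjusted over the list alone, and the list was not called, with a median of 0.16 and a mean of 0.14 against a lower camera direction and with a median of -0.02 under quantile normalization. Kdr, a VEGF receptor, rose from 0.403 ± 0.339 (0.207 without Syndecan-2- library 1) to 3.26 ± 0.518 CPM, Eng, a TGF-beta coreceptor, from 38.6 ± 0.273 to 69.5 ± 6.36 CPM and Stab2, a scavenger receptor, from 0.354 ± 0.131 to 1.56 ± 0.375 CPM. Egfl7, a secreted vessel factor, fell from 48.2 ± 7.003 to 14.8 ± 0.962 CPM and Pecam1, a junction protein gene, from 57.0 ± 2.00 to 29.6 ± 4.76 CPM. Of 4 stromal genes tested, too few for a set test, 2 rose, 1 fell and 1 was not called, with 2 and 2 adjusted over the list alone and with a median of -0.03 against a mean of 0.10. Pdgfrb, a growth factor receptor, fell from 32.1 ± 2.16 to 8.74 ± 1.16 CPM. Col1a2, a collagen gene, stood at 0.193 ± 0.123 and 6.66 ± 7.68 CPM and was called higher, with 15.5 CPM in Syndecan-2+ library 3 and a mean of 2.22 CPM without it. Fn1, fibronectin, rose from 1.15 ± 0.410 to 3.02 ± 1.29 CPM (log2 0.87), a call lost under quantile normalization (0.70, adjusted p = 0.0519) and without Syndecan-2- library 1 (0.74) or Syndecan-2+ library 2 (0.63). Spp1, osteopontin, at 2.30 ± 1.93 (1.19 without Syndecan-2- library 2) and 0.590 ± 0.378 CPM, was not called (adjusted p = 0.0540, or 0.00461 with the replicate number as a block). Spp1 was called lower with pseudocount 0.1, under quantile normalization and with the 6 libraries compared alone (adjusted p = 0.0410 to 0.0431). The same held without Parent library 1 or 2 or Syndecan-2- library 1 or 3 (adjusted p = 0.0265 to 0.0494).

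Of 8 basophil, mast cell and eosinophil genes tested, 1 rose, 0 fell and 7 were not called, with 1 and 0 adjusted over the list alone, and the list was not called. Prg2, an eosinophil granule protein gene, rose from 0.0514 ± 0.0508 (0.0263 without Syndecan-2- library 2) to 2.36 ± 1.04 CPM. Il1rl1, the IL-33 receptor, at 6.25 ± 1.12 and 8.76 ± 1.11 CPM was not called (adjusted p = 0.0556, or 0.0155 with the replicate number as a block). It was called higher with the 6 libraries compared alone (adjusted p = 0.0483) and without Parent library 2 (adjusted p = 0.0435), Syndecan-2- library 3 (adjusted p = 0.0477) or Syndecan-2+ library 2 (adjusted p = 0.0410), as were Hdc, the histamine enzyme (adjusted p = 0.0240), and Fcer1a, an IgE receptor chain (adjusted p = 0.0479), without Syndecan-2+ library 3. Of 13 dendritic cell and MHC class II genes tested, 4 rose, 4 fell and 5 were not called, with 4 and 5 adjusted over the list alone. The list was not called in camera, but was called lower in fry (adjusted p = 0.0211) and in camera without Syndecan-2+ library 2 (adjusted p = 0.0260). H2-Eb1, a class II beta chain, rose from 3.03 ± 0.677 to 7.02 ± 3.95 CPM (log2 0.86), a call lost under TMM rescaling (0.77), quantile normalization (0.68), without a filter on low values (adjusted p = 0.0522) and without Syndecan-2- library 1 (0.89) or 3 (0.73) or Syndecan-2+ library 2 (0.52) or 3 (0.74). Cd74, the invariant chain, rose from 12.8 ± 1.28 to 33.0 ± 9.05 CPM, H2-Aa, a class II alpha chain, from 4.23 ± 0.355 to 9.10 ± 3.04 CPM and Zbtb46, a dendritic cell transcription factor, from 0.472 ± 0.281 to 2.90 ± 0.696 CPM. H2-Ob, a class II loading regulator, fell from 41.6 ± 3.04 to 8.67 ± 0.992 CPM, H2-DMa from 22.1 ± 0.410 to 13.0 ± 0.523 CPM, and Ccr9, a homing receptor, from 11.1 ± 3.72 to 1.96 ± 0.628 CPM. Of 28 interferon response genes tested, 4 rose, 7 fell and 17 were not called, with 5 and 8 adjusted over the list alone, and the list was called lower only without Syndecan-2- library 1 (adjusted p = 0.0430) or Syndecan-2+ library 3 (adjusted p = 0.0457). Iigp1, an interferon-induced GTPase, rose from 8.35 ± 0.717 to 18.0 ± 0.416 CPM and Gbp2, a guanylate binding protein gene, from 10.9 ± 0.526 to 18.0 ± 1.26 CPM. Gbp3 fell from 26.7 ± 2.74 to 16.7 ± 1.02 CPM and Ifi27, a mitochondrial interferon target, from 14.5 ± 0.760 to 7.28 ± 1.03 CPM.

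Of 26 immediate-early and heat shock genes tested, 8 rose, 1 fell (Dusp2) and 17 were not called, with 8 and 1 adjusted over the list alone, with 4 higher and 2 lower under TMM rescaling and with 12 higher and 7 lower with the replicate number as a block. The list was not called. Klf4, a transcription factor, rose from 38.2 ± 8.05 to 73.0 ± 13.2 CPM, Egr1, an early response factor, from 435 ± 45.5 to 671 ± 83.7 CPM, and the phosphatase gene Dusp1 from 167 ± 27.1 to 252 ± 47.0 CPM. Of 21 TGF-beta and BMP signalling genes tested, 8 rose, 2 fell (Smad7 and Tgif1) and 11 were not called, with 9 and 3 adjusted over the list alone, and the list was not called in camera but was called higher in fry (adjusted p = 0.00685). Tgfbr3, the betaglycan coreceptor, rose from 15.9 ± 1.92 to 75.5 ± 4.75 CPM, Ski, a SMAD repressor, from 31.2 ± 1.53 to 67.9 ± 2.67 CPM and the related Skil from 27.5 ± 7.03 to 57.1 ± 12.6 CPM. Tgif1 fell from 28.4 ± 1.77 to 14.5 ± 1.76 CPM. Of 22 adhesion and homing genes tested, 8 rose, 8 fell and 6 were not called, with 9 and 8 adjusted over the list alone. That list was not called, with a median of 0.08 and a mean of 0.09 against a lower camera direction, and with a median of -0.04 under TMM rescaling. Cd9, a tetraspanin, rose from 5.74 ± 0.891 to 25.4 ± 1.04 CPM. Itgal, the LFA-1 integrin subunit, fell from 63.4 ± 2.35 to 14.9 ± 2.65 CPM, Itgb5 from 11.05 ± 1.67 to 2.12 ± 0.160 CPM and Selplg, the P-selectin ligand, from 81.0 ± 5.21 to 40.5 ± 1.49 CPM.

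Of 19 glycolysis genes tested, 7 rose, 3 fell (Pgam1, Pkm and Pdk1) and 9 were not called, with 7 and 3 adjusted over the list alone, and the list was not called in camera but was called higher in fry (adjusted p = 0.0198), with a median of 0.07, or -0.05 under TMM rescaling. Hk1, hexokinase, rose from 77.9 ± 0.354 to 143 ± 11.6 CPM, Slc2a3, a glucose transporter, from 29.3 ± 3.14 to 60.1 ± 7.03 CPM and Ldha from 102 ± 8.96 to 139 ± 6.23 CPM, while Pgam1, a mutase, fell from 62.1 ± 1.13 to 34.0 ± 3.84 CPM. Of 78 nuclear oxidative phosphorylation genes tested, 5 rose, 3 fell and 70 were not called, with 0 and 1 adjusted over the list alone, with 0 higher and 4 lower under TMM rescaling or quantile normalization and with 12 higher and 3 lower with the replicate number as a block. The list was not called, with a median of 0.09, or -0.02 under either scaling. Cox6a2, a cytochrome oxidase subunit, fell from 3.21 ± 0.261 to 0.291 ± 0.257 CPM (0.194 without Syndecan-2+ library 1) and Atp5sl, an assembly factor, from 13.5 ± 0.484 to 9.61 ± 0.492 CPM. The rises of Atp5h, Cox7a2, Cox7c, Ndufs4 and Ndufv3 were at log2 values of 0.23 to 0.42 and were lost under TMM rescaling and quantile normalization. Leaving out 1 library also lost the calls of Cox7a2 (0.32 to 0.41 without Syndecan-2- library 1 or 2 or Syndecan-2+ library 1 or 2), Cox7c (0.33 to 0.40 without Syndecan-2- library 1 or 2 or Syndecan-2+ library 2 or 3), Ndufs4 (0.32 without Syndecan-2+ library 3), Ndufv3 (0.24 to 0.35 without Syndecan-2- library 1 or 2 or Syndecan-2+ library 1 or 3) and Atp5h (0.19 to 0.26 without Parent library 1, Syndecan-2- library 2 or 3 or any 1 Syndecan-2+ library). The call of Atp5h was also lost with pseudocount 0.1 (adjusted p = 0.0517) and without a filter on low values (adjusted p = 0.0608). The fall of Sdhb was lost without Syndecan-2+ library 3 (-0.25) and without Syndecan-2- libraries 1 or 3 (-0.33). Pkm lost its call without Syndecan-2+ library 1 (-0.18).

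Of 13 mitochondrially encoded genes tested, 11 rose, 0 fell and 2 (mt-Atp8 and mt-Co2) were not called, with 13 and 0 adjusted over the list alone, with 3 higher and 0 lower under TMM rescaling and with 13 higher and 0 lower with the replicate number as a block (mt-Atp8 at adjusted p = 0.0271 and mt-Co2 at adjusted p = 0.0101). Both were also called with the 6 libraries alone and without Parent library 3, and mt-Co2 without Parent library 1 (0.23 each). Camera called the list (adjusted p = 0.00406), with an adjusted p = 0.608 with an estimated correlation. The respiratory chain genes mt-Nd3 and mt-Cytb rose from 19.2 ± 0.613 to 30.2 ± 3.62 CPM and from 302 ± 25.9 to 409.7 ± 17.1 CPM, while the call of mt-Nd5 (log2 0.27) was lost under TMM rescaling (0.15) and without Syndecan-2- library 3 (0.25) or Syndecan-2+ library 3 (0.24). Of 77 cytosolic ribosomal protein genes tested, 1 rose, 0 fell and 76 were not called, with 0 and 0 adjusted over the list alone, with 0 higher and 6 lower under TMM rescaling and with 7 higher and 1 lower with the replicate number as a block. That list was not called, with a median and mean of 0.06 against a lower camera direction, and its median was -0.06 under TMM rescaling. Rpl13, the gene called, stood at 107 ± 6.84 and 125 ± 4.26 CPM (log2 0.22, or 0.10 and not called under TMM rescaling), and it lost its call without Syndecan-2- library 2 (0.19) or 3 (0.20) or Syndecan-2+ library 3 (0.19). Rps24, at 136 ± 3.30 and 119 ± 10.6 CPM, was not called (adjusted p = 0.0699) but was called lower under TMM rescaling (adjusted p = 0.00353), with the block (adjusted p = 0.0322) and without Syndecan-2+ library 3 (adjusted p = 0.0202). Rpl38 (log2 0.34) was called higher with the block (adjusted p = 0.00904), with the 6 libraries compared alone (adjusted p = 0.0445) and without Parent library 1 or 2, Syndecan-2- library 1 or Syndecan-2+ library 2 (adjusted p = 0.0253 to 0.0482). Of 4 sex chromosome genes tested, all Y-linked, 0 were called in each of the 3 comparisons. Ddx3y stood at 26.8 ± 1.12 and 29.1 ± 2.33 CPM and Kdm5d at 16.9 ± 1.90 and 15.9 ± 1.96 CPM, while Xist, of the inactive X chromosome, was at most 0.634 CPM in any library.

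Camera called 9 of 21 lists in this comparison, and 3 hold with an estimated correlation, the long-term HSC, megakaryocyte and B, T and NK cell lists. Other splits of these libraries gave up to 13 lists in camera but 0 genes. Each mixes both populations, so they cannot rank gene counts over list calls. Fry, which tests whether the genes of a set move on balance in 1 direction and does not compare them with other genes, called 12 lists here, 9 in Syndecan-2+ against Parent and 4 in Syndecan-2- against Parent.

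**Figure D2:**
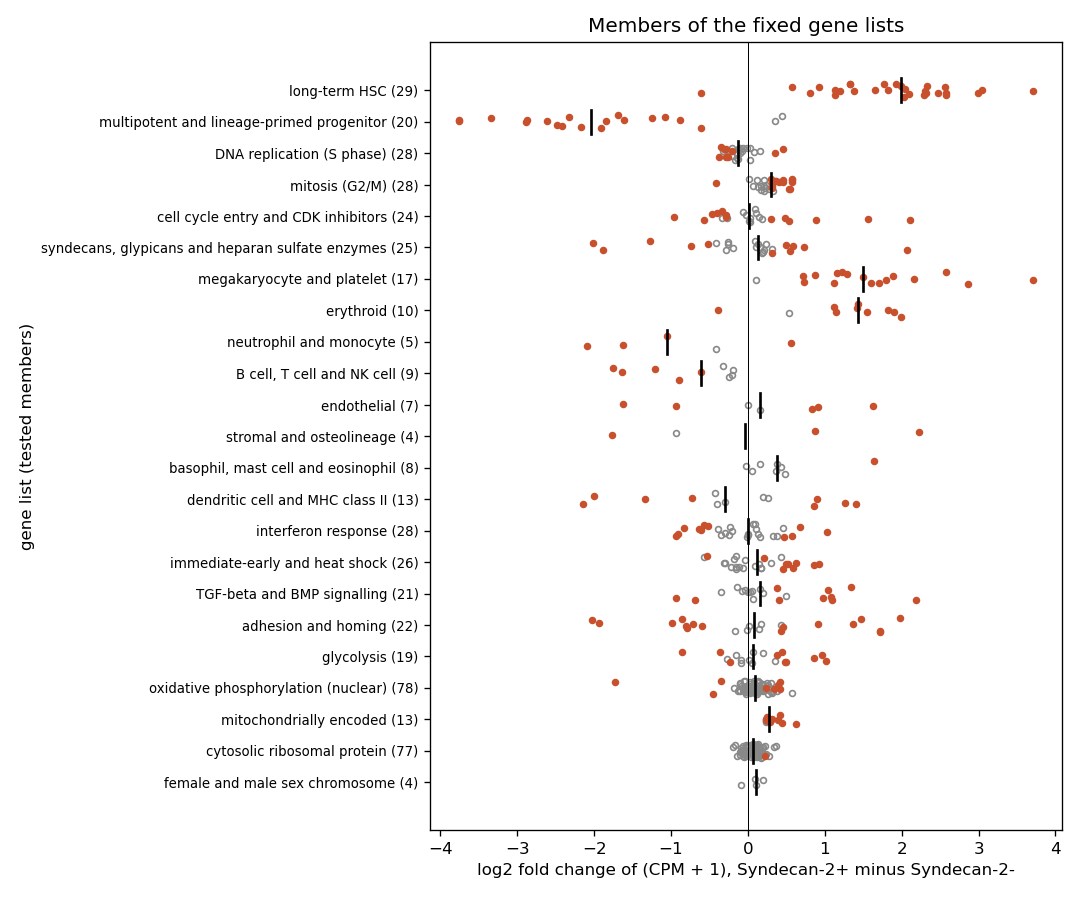
Log2 fold change of the members of each gene list, Syndecan-2+ minus Syndecan-2-, with the median as a bar and a dot per member tested, filled where the gene was called. The median is 2.00 for the long-term HSC list and -2.04 for the progenitor list.

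Syndecan-2+ against Parent asks how the sorted fraction differs from the whole gate. Stem cell genes were again higher and progenitor genes lower. Vwf rose from 26.0 ± 1.499 to 94.2 ± 11.2 CPM (log2 1.81, SE 0.11, adjusted p = 3.60e-09), and Flt3 fell from 219.9 ± 13.8 to 19.9 ± 3.16 CPM (log2 -3.41, SE 0.09, adjusted p = 2.43e-13). Igkc rose from 96.6 ± 17.2 to 428 ± 90.5 CPM (log2 2.13, SE 0.24, adjusted p = 5.24e-06). Of 13997 genes, 2409 changed, 1386 higher and 1023 lower, with 267 and 249 at 2-fold or more in CPM plus 1. The split was 1196 higher and 1241 lower under TMM rescaling and 1219 and 1208 under quantile normalization. It was 1460 and 1525 under TMM rescaling with the replicate block, and 1846 and 1279 of 3125 with the block alone. With transcripts in place of genes it was 416 higher and 548 lower, which turns the balance. With a minimum of 10 CPM it was 790 and 717.

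The largest rises were immunoglobulin genes. Iglc1 stood at 4.14 ± 6.95 CPM in Parent, where library 2 held 12.2 CPM and the mean was 0.129 CPM without it, and rose to 46.3 ± 15.2 CPM. Iglv1 rose from 1.49 ± 1.97 (0.355 without Parent library 2) to 15.7 ± 0.556 CPM, Igkv1-135 from 3.82 ± 3.24 (1.99 without Parent library 1) to 32.3 ± 21.7 CPM (19.8 without Syndecan-2+ library 1) and Ighv1-22 from 0.0899 ± 0.156 (0 without Parent library 1) to 9.06 ± 5.69 CPM (5.79 without Syndecan-2+ library 1). Igkv6-32 was listed at 0 in Parent libraries and at 6.12 ± 2.15 CPM in Syndecan-2+, at least 33.4-fold higher against a floor of 3 reads per library. The largest falls were Flt3, Dntt (from 356 ± 15.4 CPM), Sema3d (from 12.3 ± 0.841 CPM), Csf1r (from 18.6 ± 2.54 CPM) and Cd33 (from 13.5 ± 3.17 CPM).

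Of 29 long-term HSC genes tested, 27 rose, 1 fell (Hoxa9) and 1 was not called (Hoxb5), with 28 and 1 adjusted over the list alone. Fgd5 rose from 11.2 ± 1.31 CPM in Parent by 1.40 on the log2 scale (SE 0.13), Mecom from 28.0 ± 2.98 CPM by 1.26 (SE 0.10) and Procr from 6.45 ± 0.719 CPM by 0.94 (SE 0.14). Of 20 progenitor genes tested, 0 rose, 18 fell and 2 (Elane and Ms4a3) were not called, with 0 and 18 adjusted over the list alone. Satb1 fell from 148 ± 6.69 CPM by 2.54 on the log2 scale (SE 0.07) and Cd34 from 174 ± 4.34 CPM by 1.95 (SE 0.09). Of 17 megakaryocyte genes tested, 15 rose, 0 fell and 2 (Selp and Plek) were not called, with 15 and 0 adjusted over the list alone. Itga2b rose from 69.4 ± 1.84 CPM by 1.13 (SE 0.07) and Zfpm1 from 148 ± 10.5 CPM by 1.04 (SE 0.07). Of 10 erythroid genes tested, 8 rose, 1 fell (Tfrc) and 1 was not called (Tspo2), with 9 and 1 adjusted over the list alone. Tspo2 was called higher with the block (log2 0.70, adjusted p = 0.0221, against adjusted p = 0.0614 without it). Car2 rose from 109.7 ± 6.89 CPM by 0.85 (SE 0.08) and Aqp1 from 21.2 ± 3.47 CPM by 1.03 (SE 0.12). Tfrc lost its call without Parent library 1 or 3 or Syndecan-2+ library 3 (-0.31 to -0.26). Tspo2 was also called with the 6 libraries alone and without Syndecan-2- library 1 (0.70 each).

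Camera called 7 of 21 lists in this comparison, and the long-term HSC (adjusted p = 0.0455), progenitor (adjusted p = 0.0482) and megakaryocyte (adjusted p = 0.0455) lists hold with an estimated correlation. The other called lists were erythroid (adjusted p = 0.245 with an estimated correlation), DNA replication (adjusted p = 0.381), neutrophil and monocyte (adjusted p = 0.238) and B, T and NK cell (adjusted p = 0.0730). The B, T and NK cell call was also lost without a filter on low values (adjusted p = 0.135).

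Of 28 DNA replication genes tested, 0 rose, 6 fell and 22 were not called, with 1 and 8 adjusted over the list alone, and Mcm6 fell from 233 ± 8.44 CPM by 0.30 (SE 0.06) and Uhrf1 from 90.1 ± 1.06 CPM by 0.36 (SE 0.07). Of 28 mitosis genes tested, 5 rose, 1 fell (Kif23) and 22 were not called, with 5 and 1 adjusted over the list alone. That list was not called in camera, but was called higher with the block (adjusted p = 0.0373) or no filter (adjusted p = 0.0260). The same held without Parent library 1 or 2, Syndecan-2- library 3 or Syndecan-2+ library 3 (adjusted p = 0.00201 to 0.0498). Hmmr rose from 21.01 ± 1.89 CPM by 0.48 (SE 0.10) and Ccnb1 from 11.5 ± 1.77 CPM by 0.43 (SE 0.12), with Ccnb2, Ccna2 and Tpx2 as the others. Mki67 stood at 435 ± 25.2 and 509 ± 54.6 CPM and was not called (adjusted p = 0.0667, or 0.00932 with the block). Of 24 cell cycle entry genes tested, 4 rose (Cdkn1c, Cdkn2d, Rbl2 and Mycn), 5 fell (Cdkn1b, Gfi1, Cdk4, Cdk6 and Myc) and 15 were not called, with 4 and 7 adjusted over the list alone. Cdkn1c rose from 2.88 ± 1.16 CPM by 1.24 (SE 0.23). Cdkn1a stood at 16.7 ± 1.92 and 12.8 ± 1.45 CPM and was not called (adjusted p = 0.0631, or 0.0180 with the block), nor was Ly6a at 5.31 ± 0.723 and 7.54 ± 0.916 CPM (adjusted p = 0.0706, or 0.0349 with the block). Cdkn1a was called lower under TMM rescaling, quantile normalization and without Parent library 1 or Syndecan-2- library 3 (adjusted p = 0.0348 to 0.0492). Ccna2, Ccnb1 and Ccnb2 lost their calls without Parent library 2 or 3 or Syndecan-2+ library 1 or 2 (0.25 to 0.43). Tpx2 lost its call under TMM rescaling (0.25) and without any 1 Parent library or Syndecan-2+ library 1 or 2 (0.25 to 0.31). Cdk4 and Cdk6 lost their calls without Parent library 1 or Syndecan-2+ library 3 (-0.30 to -0.23). Cdkn1b lost its call without Parent library 1 or Syndecan-2+ library 1 or 3 (-0.27 to -0.22). Cdkn2d lost its call without Parent library 2 or Syndecan-2+ library 3 (0.45). Rbl2 lost its call under TMM rescaling (0.21) and without Parent library 1 or 2 or Syndecan-2+ library 2 or 3 (0.23 to 0.25). Myc lost its call without Parent library 3 or Syndecan-2+ library 2 (-0.42 to -0.37).

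Of 25 proteoglycan and heparan sulfate genes tested, 2 rose (Sdc2 and Hs3st1), 7 fell and 16 were not called, with 5 and 8 adjusted over the list alone, with 1 higher and 8 lower under TMM rescaling or quantile normalization, with 1 and 4 without a filter on low values, a median of 0.03 and a mean of -0.12, and fry called the list lower (adjusted p = 0.0484). Sdc1 fell from 14.1 ± 1.25 CPM by 1.64 (SE 0.14) and Hpse from 4.42 ± 0.499 CPM by 1.52 (SE 0.18). Of 5 neutrophil and monocyte genes tested, Lyz2 rose, Itgam, Csf3r and Ccr2 fell and Ly6c2 was not called, with 1 and 3 adjusted over the list alone. Of 9 B, T and NK cell genes tested, 0 rose, 3 fell (Ebf1, Pax5 and Lck) and 6 were not called, with 0 and 5 adjusted over the list alone. Of 7 endothelial genes tested, Kdr, Stab2 and Eng rose, Egfl7 and Pecam1 fell and 2 were not called, with 3 and 2 adjusted over the list alone, and of 4 stromal genes tested Col1a2 rose, Pdgfrb fell and 2 were not called, with 2 and 1 adjusted over the list alone. Of 8 basophil and mast cell genes tested, 1 rose (Prg2) and 7 were not called, with 1 and 0 adjusted over the list alone. Of 13 dendritic cell and MHC class II genes tested, 3 rose (H2-Aa, Cd74 and Zbtb46), 4 fell (H2-DMa, H2-Ob, Itgax and Ccr9) and 6 were not called, with 3 and 4 adjusted over the list alone, and the list was called lower in fry (adjusted p = 0.0451) and, in camera, without Syndecan-2+ library 2 (adjusted p = 0.0180). Of 28 interferon genes tested, 4 rose (Ifit2, Ifitm3, Gbp2 and Iigp1), 8 fell and 16 were not called, with 4 and 8 adjusted over the list alone, and the list was called lower only without Parent library 1 (adjusted p = 0.0377) or Syndecan-2+ library 3 (adjusted p = 0.0223). Hs3st1 lost its call with pseudocount 0.1 (1.04), without a filter and with the 6 libraries alone (0.66), under TMM rescaling (0.63), under quantile normalization (0.60) and without any 1 Parent library, Syndecan-2- library 1 or 3 or Syndecan-2+ library 2 or 3 (0.52 to 0.76). Lyz2 lost its call without Parent library 1 or Syndecan-2+ library 1 or 3 (0.29 to 0.31). Ebf1 lost its call without Parent library 2 or Syndecan-2+ library 2 or 3 (-0.71 to -0.65). Pax5 lost its call without Parent library 2 or 3 or Syndecan-2+ library 3 (-0.97 to -0.85). H2-Aa lost its call under quantile normalization (0.61) and without Parent library 2 or 3 or Syndecan-2+ library 2 or 3 (0.50 to 0.71). Zbtb46 lost its call with pseudocount 0.1 (1.13) and without Parent library 2 or Syndecan-2+ library 2 (0.63 to 0.69). Itgax lost its call without Parent library 2 or 3 or Syndecan-2+ library 1 (-0.90 to -0.67). Ifitm3 lost its call with pseudocount 0.1 and without a filter (0.32), under TMM rescaling (0.27) and without Parent library 2 or 3, Syndecan-2- library 1 or any 1 Syndecan-2+ library (0.25 to 0.36).

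Of 26 immediate-early and heat shock genes tested, 4 rose (Egr1, Dusp1, Klf4 and Klf6), 1 fell (Dusp2) and 21 were not called, with 4 and 1 adjusted over the list alone and with 0 higher and 2 lower under TMM rescaling and 6 higher and 4 lower with the block. Of 21 TGF-beta and BMP genes tested, 3 rose (Tgfbr3, Skil and Ski), 2 fell (Smad7 and Tgif1) and 16 were not called, with 5 and 2 adjusted over the list alone, and Tgfbr3 rose from 30.5 ± 1.97 CPM by 1.28 (SE 0.09). Of 22 adhesion genes tested, 7 rose, 7 fell and 8 were not called, with 7 and 7 adjusted over the list alone, a median of 0.05 and a mean of -0.04, and Cd9 rose from 12.3 ± 1.81 CPM by 1.00 (SE 0.13) while Itgal fell from 47.6 ± 3.88 CPM by 1.63 (SE 0.11). Of 19 glycolysis genes tested, 4 rose (Hk1, Aldoc, Ldha and Slc2a3), 2 fell (Pgam1 and Pdk1) and 13 were not called, with 7 and 5 adjusted over the list alone, with 3 higher and 4 lower under TMM rescaling, 3 and 2 under quantile normalization and 2 and 2 without a filter on low values. Of 78 oxidative phosphorylation genes tested, 1 rose (Atp5g2), 1 fell (Cox6a2) and 76 were not called, with 0 and 1 adjusted over the list alone. None of the 13 mitochondrially encoded and 77 ribosomal protein genes tested was called, over all genes or adjusted over the list alone, while 2 of the former rose with the replicate number as a block. Egr1 lost its call without a filter (0.32), under TMM rescaling (0.27), under quantile normalization (0.31) and without Parent library 1 or 2 or Syndecan-2+ library 1 or 3 (0.22 to 0.35). Dusp1 and Klf4 lost their calls under TMM rescaling (0.34 and 0.41) and without Parent library 1 or 3 or Syndecan-2+ library 2 or 3 (0.25 to 0.45). Klf6 lost its call with pseudocount 0.1, without a filter and with the stricter filter (0.32), with pseudocount 5 (0.31), under TMM rescaling (0.27), under quantile normalization (0.28) and without Parent library 1 or 3, Syndecan-2- library 1 or Syndecan-2+ library 2 or 3 (0.21 to 0.32). Skil lost its call without Parent library 1 or 2 or Syndecan-2+ library 1 or 3 (0.49 to 0.63). Smad7 lost its call without Parent library 3 or Syndecan-2+ library 1 or 2 (-0.45 to -0.36). Aldoc lost its call with pseudocount 0.1 (0.87), without a filter (0.63), under quantile normalization (0.54) and without Parent library 1 or 2 or Syndecan-2+ library 1 or 3 (0.52 to 0.65). Ldha lost its call without a filter (0.22), under TMM rescaling (0.17) and without any 1 Parent library, Syndecan-2- library 3 or any 1 Syndecan-2+ library (0.18 to 0.25). Atp5g2 lost its call without Parent library 2 or 3 or Syndecan-2+ library 2 or 3 (0.75 to 0.95).

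Syndecan-2- against Parent asks what the gate loses when Syndecan-2+ cells are left out. Antibody and stem cell genes fell. Igkc fell from 96.6 ± 17.2 to 0.507 ± 0.792 CPM (0.0508 without Syndecan-2- library 3, log2 -6.12, SE 0.24, adjusted p = 5.22e-11), Jchain from 25.8 ± 4.73 to 0.365 ± 0.398 CPM (0.152 without Syndecan-2- library 3, log2 -4.32, SE 0.18, adjusted p = 1.53e-10) and Vwf from 26.0 ± 1.499 to 6.28 ± 0.959 CPM (log2 -1.90, SE 0.11, adjusted p = 9.72e-09). Of 13997 genes, 373 changed, 17 higher and 356 lower, with 2 (Gm24029 and Gm17305) and 94 at 2-fold or more in CPM plus 1. The split was 48 higher and 262 lower under TMM rescaling and 181 and 431 with the block added. It was 72 and 613 of 685 with the block alone. With transcripts in place of genes, 1 was higher and 41 lower. The count of genes fell to 218 without Parent library 1, 234 without Parent library 3 and 235 without Syndecan-2- library 2. Gm24029 lost its call with pseudocount 0.1 (2.65) and without Parent library 2 or 3 (0.97 to 1.00).

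Igha was at 29.1 ± 7.16 CPM in Parent and listed at 0 in Syndecan-2- libraries, so that Parent was at least 186-fold higher against a floor of 3 reads per library. Igkv14-126 was at 8.26 ± 1.44 CPM in Parent and listed at 0 in Syndecan-2-, with Parent at least 52.8-fold higher, and Ighv11-2 was at 6.66 ± 1.35 CPM and listed at 0, with Parent at least 42.6-fold higher. The named rises were small. Ebf1 rose from 2.12 ± 0.332 to 5.08 ± 0.687 CPM, Ctnnd2, a catenin, from 2.52 ± 0.806 to 5.46 ± 1.43 CPM and Emp1 from 15.5 ± 1.11 to 24.6 ± 5.10 CPM. Pyhin1, an interferon-inducible DNA sensor family gene, rose from 12.4 ± 0.757 to 19.2 ± 2.01 CPM and Chdh, choline dehydrogenase, from 29.5 ± 1.86 to 40.3 ± 2.28 CPM. Each of these 5 calls was lost without Parent library 1, at log2 values of 0.95, 0.73, 0.64, 0.54 and 0.39, and without Syndecan-2- library 3, at 0.92, 0.71, 0.50, 0.51 and 0.42. Parent library 2 decided the calls of Ctnnd2, Emp1 and Chdh (0.86, 0.56 and 0.46 without it), Parent library 3 those of Ebf1, Emp1, Pyhin1 and Chdh (0.89, 0.65, 0.62 and 0.47), Syndecan-2- library 1 those of Ctnnd2 and Emp1 (0.94 and 0.55), and Syndecan-2- library 2 those of Ebf1, Ctnnd2, Pyhin1 and Chdh (0.91, 1.00, 0.61 and 0.41). The calls of Ctnnd2 and Emp1 were also lost without a filter on low values (adjusted p = 0.0742 and 0.0609), and those of Ebf1, Ctnnd2 and Emp1 with pseudocount 0.1 (adjusted p = 0.0708, 0.208 and 0.0518).

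Of 29 long-term HSC genes tested, 0 rose, 19 fell and 10 were not called, with 0 and 25 adjusted over the list alone. Fgd5 fell from 11.2 ± 1.31 to 3.06 ± 0.422 CPM, Mecom from 28.0 ± 2.98 to 13.2 ± 0.733 CPM and Procr from 6.45 ± 0.719 to 3.03 ± 0.394 CPM. Slamf1 was at 4.09 ± 0.910 and 2.54 ± 0.284 CPM and was not called (adjusted p = 0.162). Of 20 progenitor genes tested, 1 rose (Satb1), 0 fell and 19 were not called, with 9 and 0 adjusted over the list alone and with 6 higher and 0 lower with the block. Satb1 rose from 148 ± 6.69 to 187 ± 9.58 CPM. Flt3 stood at 219.9 ± 13.8 and 279 ± 16.3 CPM and was not called (log2 0.34, adjusted p = 0.0598). It was called under TMM rescaling, with pseudocount 5 and with the 6 libraries alone (adjusted p = 0.0161 to 0.0473). The same held without Syndecan-2+ library 2 or 3 and with the block (adjusted p = 0.0155 to 0.0231). With the block, Cd34 (log2 0.22, adjusted p = 0.0372), Kit (log2 -0.26, adjusted p = 0.00430) and Cdkn1c (log2 -0.87, adjusted p = 0.0125) were called too. Without the block Cdkn1c was not called (adjusted p = 0.0540), except with pseudocount 0.1 (adjusted p = 0.0361) and without Parent library 1 (adjusted p = 0.0376) or Syndecan-2- library 3 (adjusted p = 0.0224). Of 17 megakaryocyte genes tested, 0 rose, 7 fell and 10 were not called, with 0 and 9 adjusted over the list alone. Itga2b fell from 69.4 ± 1.84 to 40.6 ± 2.25 CPM, Zfpm1 from 148 ± 10.5 to 93.1 ± 5.66 CPM and Pf4 from 11.9 ± 1.54 to 4.85 ± 1.07 CPM. Of 10 erythroid genes tested, 0 rose, 4 fell (Car1, Car2, Aqp1 and Hemgn) and 6 were not called, with 0 and 7 adjusted over the list alone and with 3 lower under TMM rescaling, quantile normalization or no filter, and Car2 fell from 109.7 ± 6.89 to 67.3 ± 7.19 CPM. Satb1 lost its call without Parent library 1 or 2 or Syndecan-2- library 1 or 3 (0.29 to 0.34). Hemgn lost its call with pseudocount 5 (-0.30), without a filter and with the 6 libraries alone (-0.41), under TMM rescaling (-0.34), under quantile normalization (-0.32) and without any 1 library (-0.44 to -0.37).

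Camera called 7 of 21 lists here, and only the long-term HSC list holds with an estimated correlation (adjusted p = 0.0228). The others were progenitor (adjusted p = 0.240 with an estimated correlation), mitosis (adjusted p = 0.746), megakaryocyte (adjusted p = 0.0636), erythroid (adjusted p = 0.240), B, T and NK cell (adjusted p = 0.0636) and mitochondrially encoded (adjusted p = 0.487). The mitosis call was also lost under TMM rescaling (adjusted p = 0.165). It was lost too without Parent library 1 or 2 or Syndecan-2- library 1 or 3 (adjusted p = 0.0927 to 0.260). The neutrophil and monocyte list was called higher only without Parent library 2 (adjusted p = 0.0299) or Syndecan-2+ library 2 (adjusted p = 0.0402). The immediate-early and heat shock list (adjusted p = 0.00740) and the TGF-beta and BMP list (adjusted p = 0.0403) were called lower only with the replicate block and under quantile normalization (adjusted p = 0.0172 and 0.0498) or without 1 library, Syndecan-2- library 2 for the former (adjusted p = 0.00130) and Parent library 1 for the latter (adjusted p = 0.0292).

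None of the 28 DNA replication, 28 mitosis, 5 neutrophil and monocyte, 4 stromal, 8 basophil, 28 interferon, 26 immediate-early and heat shock, 78 oxidative phosphorylation and 77 ribosomal protein genes tested was called, and 0 were called adjusted over each list alone. With the block, 5 immediate-early and heat shock genes fell. None of the 13 mitochondrially encoded genes was called over all genes, while 0 rose and 9 fell adjusted over the list alone and 8 fell with the block. None of the 7 endothelial and 13 dendritic cell and MHC class II genes was called either, with 1 higher and 2 lower adjusted over each list alone. Ebf1 rose among 9 B, T and NK cell genes tested, with 1 and 0 adjusted over the list alone. Single falls were Sdc2 among 25 proteoglycan genes, with 0 and 1 adjusted over the list alone, and Mycn, from 33.1 ± 2.02 to 20.3 ± 0.576 CPM, among 24 cell cycle entry genes, with 0 and 2 adjusted over the list alone. Of 22 adhesion genes tested, 3 fell (Itga6, Cd9 and Cd63) and 0 rose, with 1 higher and 4 lower adjusted over the list alone. Of 21 TGF-beta and BMP genes tested, 2 fell (Tgfbr3 and Ski) and 0 rose, with 0 and 2 adjusted over the list alone, and of 19 glycolysis genes tested 2 fell (Hk1 and Slc2a3) and 0 rose, with 0 and 3 adjusted over the list alone, 0 lower under TMM rescaling and 1 lower under quantile normalization or without a filter. Tgfbr3 fell from 30.5 ± 1.97 to 15.9 ± 1.92 CPM and Hk1 from 99.97 ± 5.12 to 77.9 ± 0.354 CPM. Hk1 lost its call under TMM rescaling (-0.28) and without Parent library 3 (-0.33). Slc2a3 lost its call without a filter (-0.43), under TMM rescaling (-0.36), under quantile normalization (-0.37) and without Parent library 2 or 3 or Syndecan-2- library 1 or 3 (-0.44 to -0.35). Itga6 lost its call without Parent library 1 or Syndecan-2- library 3 (-0.53 to -0.41).

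The position of Parent describes how the whole gate lies between its parts. For 93.8% of the 4205 genes that changed between the sorted populations, the Parent mean lay between the other means, and the slope of Parent minus Syndecan-2- on Syndecan-2+ minus Syndecan-2- was 0.351 (SD 0.0234 over Parent libraries). A Parent simulated as unchanged from Syndecan-2- gave a slope of 0.0115 and 49.9% of genes between, as the mean of 100 draws. On the CPM scale the slope was 0.280. Summed CPM put Parent at 0.289 ± 0.0557 of the way to Syndecan-2+ for the long-term HSC list, 0.252 ± 0.0407 for the progenitor list and 0.210 ± 0.0148 for immunoglobulin genes and Jchain. For single genes, the position was 0.333 ± 0.0682 for Sdc2, 0.224 ± 0.0170 for Vwf, 0.228 ± 0.0533 for Flt3 and 0.225 ± 0.0403 for Igkc.

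**Figure D3:**
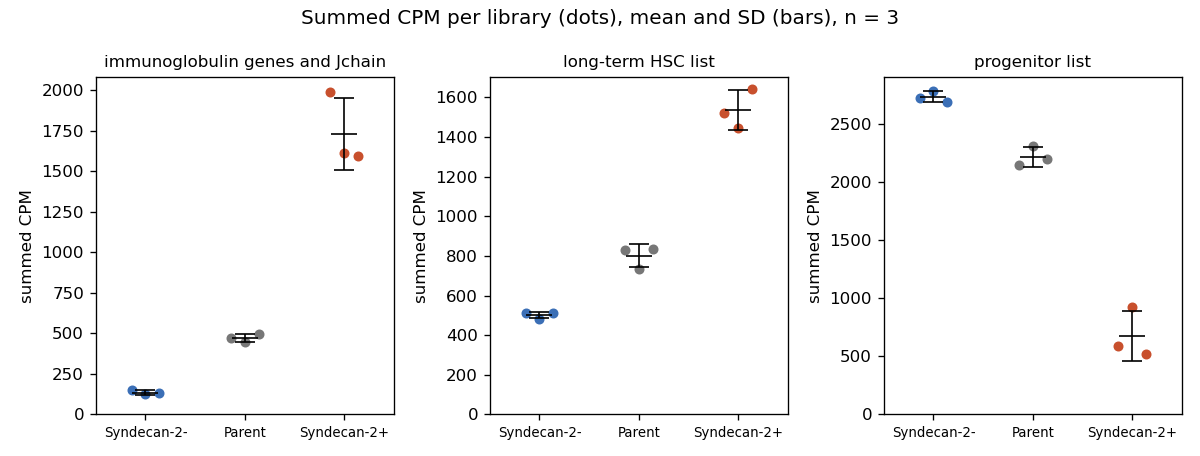
Summed CPM per library (dots) with mean and SD (bars) for immunoglobulin genes and Jchain, the long-term HSC list and the progenitor list in Syndecan-2-, Parent and Syndecan-2+ libraries. Parent lies between the other populations in each panel, at 470.4, 801 and 2219 CPM.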

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

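The tests chosen only after the result was seen are rescaling to the same listed sum, TMM rescaling together with the block, the CPM scale, quantile normalization for the lists, and leaving out libraries for Sdc2 and the position of Parent. Counts of called list members that the replicate block changed are given in the report or here, and where a cause is not named the cause was not tested.

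The naming rule favours strong changes. Of 142 called results of genes it named, 125 kept direction and call in the settings run for single genes, and 0 reversed. These were the pseudocounts, both filters, TMM rescaling, quantile normalization, the block, the 6 libraries alone and each library left out, and genes outside a filter have no value under it. Of 23 called lists 7 did so and 0 reversed, under an estimated correlation, fry, no filter, TMM rescaling, quantile normalization, the block and each library left out. Settings of eBayes, the BH threshold, transcripts, the same listed sum and TMM rescaling with the block were run for gene counts only. All reversals were in uncalled results, 12 values among 25 for genes and 53 among 40 for lists. The Sdc2 difference stayed at 3.92 to 4.45 CPM between the sorted populations, 2.51 to 3.04 CPM against Parent and -1.57 to -1.29 CPM for Syndecan-2- against Parent as libraries were left out, and 4.06, 2.66 and -1.39 CPM under TMM rescaling.

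Counts of changed genes (Syndecan-2+ against Syndecan-2-, Syndecan-2+ against Parent, Syndecan-2- against Parent) were 3983, 2437 and 310 under TMM rescaling, and 3868, 2427 and 267 under quantile normalization. Between the sorted populations these kept 3321 and 3323 of the 4205 calls, and TMM rescaling cut the higher share from 68.3% to 49.96%. A stricter filter gave 2609 and 1507 in the Syndecan-2+ comparisons, with fewer genes tested. Transcripts in place of genes gave 2533, 964 and 42, with 43.2% higher in Syndecan-2+ against Parent. The replicate block gave 4985, 3125 and 685, or 4635, 2985 and 612 with TMM rescaling. As each library was left out, the counts were 3381 to 4221, 1694 to 2413 and 218 to 369, with fewer samples.

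With the replicate block the list members called higher and lower, where these counts changed and are not in the report, were as follows. Syndecan-2+ against Syndecan-2-: progenitor 1 and 18, DNA replication 2 and 8, mitosis 18 and 1, cell cycle entry 7 and 9, proteoglycans 6 and 6, basophil 2 and 0, interferon 6 and 8, TGF-beta 9 and 3, and glycolysis 7 and 4. Syndecan-2+ against Parent: DNA replication 1 and 9, mitosis 8 and 1, cell cycle entry 5 and 9, proteoglycans 5 and 8, erythroid 9 and 1, B, T and NK cell 0 and 4, basophil 2 and 0, TGF-beta 6 and 3, glycolysis 5 and 5, oxidative phosphorylation 5 and 2, and ribosomal protein 1 and 0. Syndecan-2- against Parent: long-term HSC 0 and 20, cell cycle entry 0 and 2, erythroid 0 and 6, endothelial 0 and 1, dendritic cell 0 and 1, TGF-beta 0 and 4, adhesion 1 and 3, glycolysis 0 and 3, and ribosomal protein 0 and 1. The balance of members called also turned or levelled in these lists. Syndecan-2+ against Syndecan-2-: dendritic cell 3 and 5 under TMM rescaling and 3 and 6 under quantile normalization, and without a filter cell cycle entry 6 and 6 and ribosomal protein 1 and 1. Syndecan-2+ against Parent: TGF-beta 3 and 3 under TMM rescaling, oxidative phosphorylation 1 and 2 there and 1 and 3 under quantile normalization, and ribosomal protein 0 and 1 under TMM rescaling or without a filter.

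List calls fell from 9, 7 and 7 to 3, 3 and 1 with an estimated correlation (the cause was not tested), and fry called 4 lists in Syndecan-2- against Parent. The slope of Parent was 0.280 on the CPM scale and 0.339 to 0.364 as libraries were left out.

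Under TMM rescaling these uncalled values reversed. Syndecan-2- against Parent: Cdkn1a 0.0465, Mki67 0.000669, the ribosomal protein list 0.00995 and the proteoglycan list -0.0314. Syndecan-2+ against Syndecan-2-: Ddx3y -0.00831, Eif2s3y -0.0248, the endothelial list 0.0559 and the oxidative phosphorylation list -0.0246. Syndecan-2+ against Parent: the endothelial list 0.260, the glycolysis list 0.0272 and the oxidative phosphorylation list -0.00901. For lists the value is the median, and a reversal is that of the test's direction. Under quantile normalization Cdkn1a in Syndecan-2- against Parent was at 0.0453, Eif2s3y at -0.0400, and the ribosomal protein list at 0.00181. The endothelial list was at -0.0180 between the sorted populations and 0.213 against Parent, and the oxidative phosphorylation list at -0.0185 and -0.00620.

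In fry, which does not compare with other genes, the direction differed from camera for lists of unchanged median. These were, in Syndecan-2+ against Syndecan-2-, adhesion 0.0786, cell cycle entry 0.0189, ribosomal protein 0.0641 and endothelial 0.157. In Syndecan-2+ against Parent it was endothelial 0.3001, and in Syndecan-2- against Parent DNA replication -0.0121, dendritic cell 0.0790, endothelial 0.0205, interferon -0.0529, oxidative phosphorylation -0.0565 and proteoglycans -0.0767. Without a filter the endothelial list reversed at 0.3001 against Parent and 0.272 between the sorted populations, and the interferon list at -0.0529 and the oxidative phosphorylation list at -0.0569 in Syndecan-2- against Parent. With the block the immediate-early and heat shock list reversed at -0.0150 in Syndecan-2+ against Parent.

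Ranges over libraries left out, for uncalled results that reversed in at least 1, were as follows. Syndecan-2- against Parent: Cdkn1a -0.138 to 0.0710, Ly6a -0.0951 to 0.108, adhesion -0.128 to -0.0484, ribosomal protein -0.109 to -0.0135, immediate-early and heat shock -0.287 to -0.0531, interferon -0.101 to 0.0194, oxidative phosphorylation -0.0831 to -0.0131 and proteoglycans -0.0987 to -0.0596. Syndecan-2+ against Parent: basophil -0.146 to 0.355, glycolysis 0.0304 to 0.0847, immediate-early and heat shock -0.134 to 0.197, mitochondrially encoded -0.0460 to 0.124 and oxidative phosphorylation 0.0257 to 0.0576. Syndecan-2+ against Syndecan-2-: Kdm5d -0.174 to 0.00278, ribosomal protein 0.0150 to 0.0849, immediate-early and heat shock -0.0407 to 0.371 and oxidative phosphorylation 0.0566 to 0.136.

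A count test was not run, since whole reads came back for only part of the values. Values under 0.146 to 0.194 CPM rest on fewer than 3 reads.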

Other observations

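The tests chosen only after the result was seen, bounds included, are those of heat shock genes by replicate number, mature B cells, entry during the sort, rescaling to the same listed sum, the 10 highest genes, Ppbp, globin genes and the splits.

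Heat shock genes differed by replicate number in all 3 populations. Mean CPM over the libraries numbered 1, 2 and 3 was 219.6, 2095 and 29.5 for Hspa1a, 295.9, 2653 and 47.0 for Hspa1b, 78.7, 348.7 and 69.3 for Hsph1, and 736.6, 1364 and 703 for Hspa8. The first component of the deviations from the population means held 28.6% of their variance, with the libraries numbered 2 at 15.3 to 15.5. With the replicate number as a block, limma called Hspa1a (log2 -0.57, SE 0.18, adjusted p = 0.0183), Hsph1 (-0.29, adjusted p = 0.0116) and Hspa8 (-0.16, adjusted p = 0.0354) lower in Syndecan-2+ than in Syndecan-2- libraries, against adjusted p = 0.819, 0.774 and 0.711 without it. Of the 6 heat shock genes looked at, Hspa1b (adjusted p = 0.203), Dnajb1 (adjusted p = 0.493) and Hsp90aa1 (adjusted p = 0.693) were not called with the block. What the numbers share is not given in the sources used here.

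Immunoglobulin genes and Jchain were higher in Syndecan-2+ libraries. Mature B cells are argued against by the median log2 fold change of -0.98 of their 4 tested markers, of which 2 fell, and entry of other cells only during the Syndecan-2+ sort by the Parent libraries, the lowest of which lies 0.195 of the way from Syndecan-2- to Syndecan-2+. Plasma cells in the gate are a candidate explanation. Of 14 markers other than immunoglobulin genes, 9 passed the filter, which Syndecan-2+ libraries alone can meet. Of these 9, 7 rose and the median was 0.65. Txndc5 stood at 25.7 and 42.4 CPM, Xbp1 at 25.3 and 38.4 CPM and Slamf7 at 0.158 and 1.93 CPM. However 4 of those markers reach 1 CPM in all Syndecan-2- libraries, Sdc1, a plasma cell marker too, fell from 17.0 to 3.91 CPM, and the lineage and c-Kit gates are meant to remove such cells. Immunoglobulin transcripts made by the sorted cells themselves stay open as an untested alternative.

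More genes were called higher than lower in Syndecan-2+ against Syndecan-2-. A difference in the share of reads in listed transcripts is argued against as the whole cause, since 59.1% of called genes were higher after rescaling to the same listed sum, against 68.3% before. A few genes taking more of the counts in Syndecan-2- are argued against by a share of the 10 highest genes that was -0.212 percentage points apart. TMM rescaling removes the excess, with 49.96% higher, but it assumes that most genes do not change. Whether cells of the populations differ in total RNA stays open and cannot be seen in CPM.

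Megakaryocyte and erythroid genes were higher in Syndecan-2+ libraries. Erythroid cells that make haemoglobin are argued against by 4 globin genes, whose summed rise was 0.849% of that of Car1 and Car2. Platelet genes Ppbp (0.0879 and 0.490 CPM, a rise 1.11% of that of Pf4), Tubb1 (0.228 and 1.01) and Clec1b (0.278 and 0.883) were low but higher. Mature megakaryocytes or platelets stay open, as does untested expression of such genes in the stem cells.

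Each comparison allows only 10 splits of its 6 libraries, too few for a share under 0.05. For Syndecan-2+ against Syndecan-2-, 1 split (the real 4205 genes, highest other 0) gave as many genes and 5 as many lists (real 9, highest other 13). For Syndecan-2+ against Parent these were 1 (2409, highest other 1) and 7 (7 lists, highest other 10), and for Syndecan-2- against Parent 1 (373, highest other 0) and 3 (7 lists, highest other 7). Every other split mixes both populations, so its counts give no chance level. The 3 that part all 3 pairs gave up to 0, 1 and 0 genes and 9, 7 and 6 lists. The 6 others part 1 pair.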
